A study of Mus musculus with 41 samples.

How the data were processed

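The series holds 41 mouse samples. Of these, 32 are RNA-seq samples of total RNA from wild-type (WT) embryonic stem cells (ESCs) of the R1 line and from Caprin1 knockout (KO) cells, and 9 are RNA immunoprecipitation sequencing (RIP-seq) samples of CAPRIN1. For RNA-seq, cells were exposed to 1 µM retinoic acid for 4 days in medium that lacked LIF, the cytokine that sustains ESCs, and then received 2 µg/ml α-amanitin for 0, 2, 4 or 8 h. The RIP-seq samples were a control, cells in retinoic acid, cells in nocodazole (10 µM for 8 h), cells in arsenate (200 µM for 2 h) and cells in ESC medium.

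The deposited RNA-seq files are 4 tables, 1 per time point, of raw counts per gene, with 1 column per library, and per the file headers a further column of another kind gives gene length in bases. Each table holds 51520 lines. Of these, 110 repeat an identifier with identical values and were dropped, which left 51410 Ensembl gene identifiers, of which 50703 matched the reference of gene symbols and positions. All values were whole numbers and column totals differed between libraries. The 4 tables hold 31 libraries: the 0 h table has no column for KO clone 4 replicate 1, so KO stands for 3 libraries at 0 h (2 of clone 2, 1 of clone 4) and for 4 at each later time, against 4 WT libraries at each time. The RIP-seq files used here are a pair of lists of gene symbols by the authors, of another kind than counts, which name the comparisons "CNT vs RA" and "2I vs RA" and give no values, direction, threshold or background. Per the submitters' processing notes, FastQC 0.11.9, STAR 2.4.0.1, TopHat, DESeq2, Cufflinks and Cuffdiff were used with GRCm38 and mm10, without saying which tool made which file. The counting program, its strand setting and the annotation release are not given in the sources used here. Counts of genes with near-identical copies (Zscan4 and Usp17l families, ribosomal protein genes and their pseudogenes) and of genes that overlap another on the opposite strand therefore depend on unstated settings.

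Total counts, given in mega-counts (M), ranged from 3.46 to 31.6 M per library. Precision differs with depth: the 0 h table averaged 18.7 ± 8.74 M (SD, n = 7) and the later tables between 7.16 and 8.62 M. Values per library are given as counts-per-million values (CPM), of the library total for Caprin1 and for shares of the library, and scaled by TMM for other genes, with the SD between libraries.

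Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood fit with robust estimation, quasi-likelihood F test). A gene was called at a Benjamini-Hochberg false discovery rate (FDR) under 0.05, with no limit on the fold change. KO was compared with WT within each time point, with genotype as the only term, so that the spread between the clones stays in the error; each clone was also compared with WT in a fit with 3 groups. Changes over time were tested in a joint fit of the 8 genotype and time groups (23 residual degrees of freedom), as 2, 4 or 8 h against 0 h within WT and within KO, as the difference of these changes between KO and WT, and as a joint F test of the 3 differences. The error of each log2 fold change is its standard error (SE), the fold change divided by the square root of edgeR's F statistic.

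Gene lists were tested against all other genes with camera of limma 3.58.1 at the preset correlation of 0.01, and again with camera's estimated correlation. They were also tested with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. Adjusted p-values of lists are over the lists of a comparison; for single members, counts are given over all genes tested and adjusted over the list alone. The 19 lists fixed before the data were examined are pluripotency, retinoic acid response, Hox genes, neuroectoderm, primitive and parietal endoderm, primitive streak and mesoderm, trophoblast, 2-cell-like, fibroblast feeder, CAPRIN1 partners and stress granule, RNA decay factors, short-lived immediate early, mitochondrially encoded, cytosolic ribosomal proteins, p53 targets, integrated stress response, cell cycle, imprinted genes and Y-linked. A further 4 lists were added after the data were examined: interferon-stimulated, antigen presentation, cholesterol synthesis, and hypoxia and glycolysis. Named members had a mean of at least 1 CPM. The RIP lists were matched by symbol: of 2170 symbols in the CNT list, 2091 matched directly and 47 through an older symbol, and of 2502 in the 2I list, 2409 and 54.

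The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Caprin1; for KO against WT at 0 h, WT 8 h against 0 h and the difference in change over 8 h, the 8 called genes with the largest increase and the 8 with the largest decrease at a mean of at least 5 CPM, without predicted genes, and for KO against WT only where each library of both clones lay on the same side of each WT library; up to 4 called members of each list, at the ends of its range; and, whatever their values, Xrn2, Xrn1, Ccnd2, Myc, G3bp1, G3bp2, Caprin2, Pou5f1, Nanog, Gata6 and Pax6. Of the genes chosen by this rule, 4 are not reported here. The rule's part on fold changes of the RIP lists could not be applied, since the lists hold none. Genes outside the rule are named as chosen after their values were seen.

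The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be partly technical. Whether replicate numbers pair libraries was checked by correlating each library's deviation from its group mean, across genes, over time and between genotypes. All 21 pairs of KO libraries of the same clone and number correlated above 0.1 over time (0.687 to 0.818), but the same number was the best match in only 11, so the KO libraries pair by cell line. In WT, 3 of 24 such pairs passed 0.1 (-0.0477 to 0.251), and between WT and KO 0 of 15 did (-0.101 to 0.0720). Replicate numbers thus do not pair WT with KO, and a fit with the replicate number as a block within a time is given only among the alternatives.

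The fits were tested on simulated data with 200 changed genes. Of genes changed by 2-fold and 4-fold, 47.0% and 87.9% were recovered for KO against WT at 0 h, 68.2% and 89.4% for WT 8 h against 0 h, and 47.0% and 80.3% for the difference in change over 8 h, while 4.90%, 3.62% and 5.15% of calls fell on unchanged genes. For KO against WT at 2 h the share of calls on unchanged genes was 10.9%, and for the difference in change over 8 h with each clone as its own group it was 9.74%. Of 100 simulated unchanged lists, camera gave p under 0.05 for 3 and fry for 5. Libraries were drawn independently around the same mean per gene, without a difference shared by the libraries of a clone. These shares therefore do not cover errors that arise when libraries of the same clone share a difference.

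Alternatives, each changing 1 choice, were DESeq2 1.42.0, size factors of the RLE kind, no filter on low counts, leaving out each library in turn, replicate or culture blocks, a mean of the clones in a 3-group fit, a joint fit over times, at least 1.5-fold change, each clone as its own group, a linear slope over hours, and scaling to the summed counts of mitochondrially encoded protein genes, whose polymerase α-amanitin does not inhibit. Fits without the 4 h libraries, with WT libraries alone, with either clone alone against WT over time, and the list tests with each clone as its own group were added after the data were examined. Random gene lists (10000 draws) were matched to the RIP lists by expression (50 bins) or by expression (20 bins) and gene length (10 bins). Since the clones share their WT libraries, their overlap was set against 10 simulated draws per time without a clone effect and against the 6 splits of the 4 WT libraries into pairs, each pair serving 1 clone.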

Results

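CAPRIN1 is a cytoplasmic RNA-binding protein that partners the stress granule proteins G3BP1 and G3BP2. The study asked how its loss affects RNA in mouse ESCs that have begun to differentiate. RNA-seq covered 31 libraries of R1 wild-type (WT) cells and of Caprin1 knockout (KO) clones 2 and 4 after 4 days in 1 µM retinoic acid, a signal that drives ESCs out of pluripotency. Cells were harvested at 0, 2, 4 and 8 h of α-amanitin, an inhibitor of RNA polymerase II. With transcription blocked, later samples would hold RNA made mostly before the drug, but the block itself was not measured in these files. Each time had 4 WT libraries and, from 2 h on, 2 libraries of each clone. At 0 h the table held 2 libraries of clone 2 and 1 of clone 4.

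Total counts per library averaged 18.7 ± 8.74 M at 0 h (SD, n = 7), 7.16 ± 0.657 M at 2 h, 7.85 ± 2.04 M at 4 h and 8.62 ± 1.09 M at 8 h (n = 8 each). The shallowest libraries were WT replicate 2 at 4 h (3.46 M) and WT replicate 1 at 0 h (3.95 M), and the deepest was clone 2 replicate 1 at 0 h (31.6 M). WT libraries fell into pairs at 0 h: the chi-square per gene between libraries was 3.62 for replicates 1 and 2 and 2.86 for replicates 3 and 4, but 18.7 to 41.4 across the pairs. The same pairs stood closest at 8 h (1.93 and 2.34, against 6.88 to 10.8 across them). At 4 h, WT replicate 1 stood apart from the other WT libraries (6.56 to 14.9).

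The Caprin1 transcript separated the clones. Caprin1 (ENSMUSG00000027184.14; GRCm38 chromosome 2, 103762945 to 103797669) had 130 ± 27.0 CPM in clone 2 (SD, n = 8), 1061 ± 78.9 CPM in libraries labelled clone 4 knockout (n = 7) and 1028 ± 107 CPM in WT (n = 16). At 0 h the log2 difference from WT was -3.06 in clone 2 (FDR 5.26e-08) and 0.28 in clone 4 (FDR 0.190). With both clones pooled it was -1.05 (SE 0.775, FDR 0.346). Counts per gene do not show whether the clone 4 transcript encodes protein, and the protein was not measured in these files. In WT, the Caprin1 level was 966 ± 109 CPM at 0 h and 1178 ± 25.1 CPM at 8 h (n = 4 each), a log2 change of 0.35. It was not called in the joint fit (SE 0.765, FDR 0.771), whose error holds the Caprin1 difference between the KO clones, and was called in a fit of WT libraries alone, chosen after the data were seen (0.34, FDR 0.000482).

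**Figure D1:**
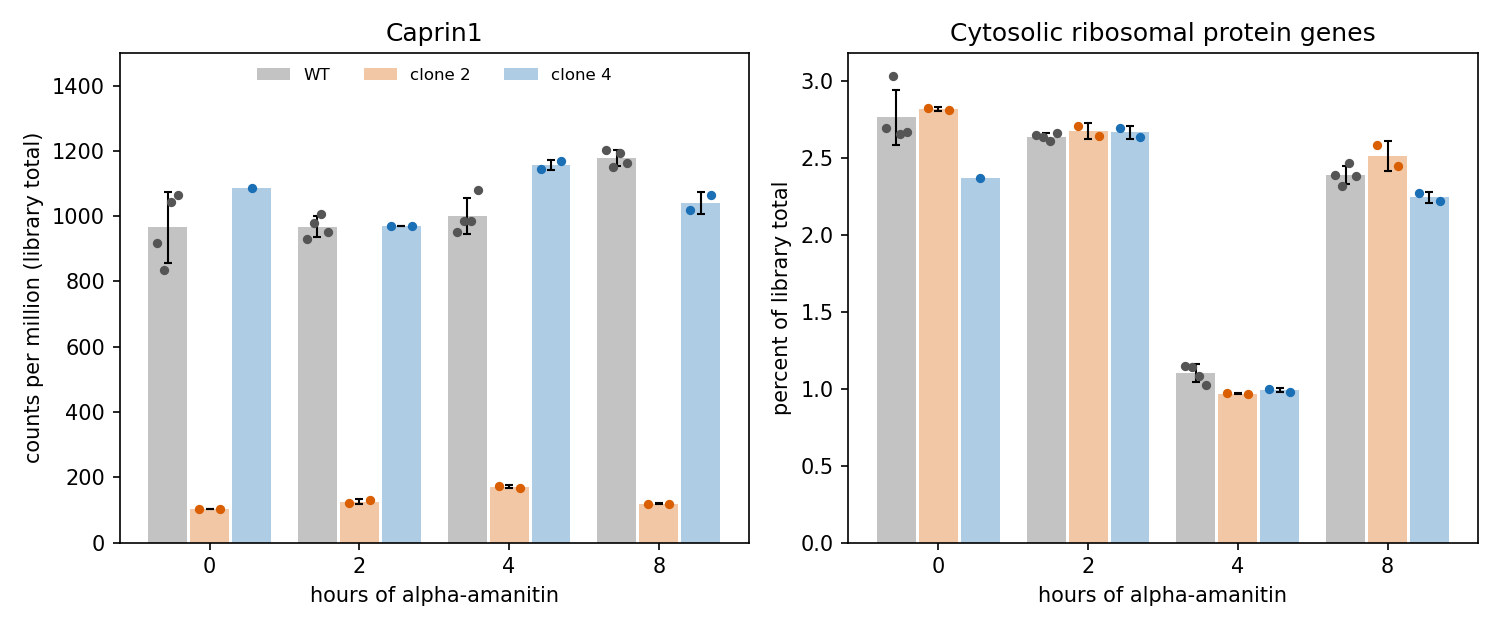
Left, Caprin1 counts-per-million of the library total (y axis) by hours of α-amanitin and cell group; right, percent of the library total in cytosolic ribosomal protein genes; bars are means, points are libraries and error bars are SD. Clone 2 lies near 130 CPM and clone 4 near 1061 CPM, and the ribosomal protein share falls to 1.04% in the 4 h table.

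The first comparison asked how RNA levels differed between KO and WT cells after retinoic acid, before α-amanitin. The largest increases included interferon-stimulated genes. Usp18, which removes ISG15 from proteins (ENSMUSG00000030107.10; chromosome 6, 121245906 to 121270917), had 15.2 ± 2.78 CPM in KO (SD, n = 3) and 0.979 ± 0.521 CPM in WT (n = 4), a log2 difference of 3.78 (SE 0.308, FDR 0.000853). Ifit1, an antiviral RNA sensor (ENSMUSG00000034459.8; chromosome 19, 34640889 to 34650009), was higher by 3.98 (SE 0.457, FDR 0.00220). As the rule for named genes required, both were higher in each clone, Usp18 by 3.70 in clone 2 and 3.84 in clone 4, and Ifit1 by 3.51 and 4.61. Nnat, an imprinted gene of the developing nervous system (ENSMUSG00000067786.16; chromosome 2, 157560078 to 157562525), was lower, at 3.24 ± 3.22 CPM in KO against 52.3 ± 11.2 CPM in WT (log2 difference -4.03, SE 0.585, FDR 0.00422).

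Other genes with large increases were the kinase gene Ptk6 (ENSMUSG00000038751.5; chromosome 2, 181195124 to 181202789; log2 4.48, SE 0.775, FDR 0.00701), the growth factor Fgf7 (3.78), the chemokine Ccl7 (3.45), Lgals3bp (3.38), the adhesion molecule Vcam1 (3.37) and the pepsinogen Pga5 (3.32). Ptk6 and Pga5 rested mainly on clone 2: their log2 differences were 5.03 and 3.83 there, and 1.31 and 0.68 in clone 4. Fgf7, higher in each clone as the rule required, differed by 3.07 in clone 2 and 4.59 in clone 4. After Nnat, other large decreases were in the matrix protein gene Hapln1 (-3.58, SE 0.997, FDR 0.0329), the signalling gene Wnt3 (-3.18), Zfp36l3 (-3.17), Slc16a12 (-3.03), the carbonic anhydrase Car3 (-2.99) and the keratin Krt7 (-2.96). These were called in each clone but were larger in clone 2 than in clone 4: Nnat -5.20 and -2.88, Hapln1 -7.65 and -1.96, Wnt3 -5.88 and -1.69, Zfp36l3 -4.49 and -1.97, Slc16a12 -5.22 and -1.62, Car3 -4.89 and -1.65, and Krt7 -3.92 and -1.91. In all, edgeR called 4092 of 15659 genes, 2180 higher and 1912 lower in KO.

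Primitive and parietal endoderm genes were higher in KO as a group: 27 of 29 measured members were higher and 0 lower (28 and 0 adjusted over the list alone, median log2 1.47, adjusted p = 2.37e-13). With an estimated correlation the adjusted p was 0.326, and likewise 0 of the 19 lists were called that way, so each call of these lists at 0 h rests on the preset correlation. Thbd, a marker of parietal endoderm, had 43.1 ± 1.61 CPM in KO against 6.98 ± 1.01 CPM in WT (log2 2.62, SE 0.138, FDR 0.000103) and the same log2 difference in both clones. Srgn (2.49; 2.90 in clone 2 and 1.02 in clone 4), P4ha2 (0.91; 1.16 and 0.28) and Plat (0.69; 0.91 and 0.18) were also higher with the clones pooled, as was the endoderm regulator Gata6 (1.18, SE 0.157, FDR 0.00328). Genes of the 2-cell-like state, a rare ESC state that resembles the early embryo, were higher in 12 of 14 cases and lower in 0 (13 and 0 adjusted over the list alone, median 1.51, adjusted p = 5.11e-08, and adjusted p = 0.114 with an estimated correlation). Among them were Zfp352 (2.22; 2.65 in clone 2 and 0.73 in clone 4), Tmem92 (2.17), Usp17le (1.17) and Zscan4e (1.07), of which the last 2 belong to families of near-identical copies.

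Pluripotency genes were higher in 15 of 31 cases and lower in 1 (17 and 2 adjusted over the list alone, median 0.41, adjusted p = 0.000647, and adjusted p = 0.292 with an estimated correlation). Klf5, which sustains ESC self-renewal, had 802 ± 346 CPM in KO against 227 ± 21.8 CPM in WT (log2 1.82, SE 0.282, FDR 0.00460). Tcl1 (1.75), Tbx3 (0.35) and Pou5f1, which encodes OCT4 (0.72, SE 0.165, FDR 0.0153), were higher and Nodal was lower (-0.74, FDR 0.0364). Nanog was not called (0.41, FDR 0.0703). Integrated stress response genes were higher in 12 of 26 cases and lower in 2 (14 and 2 adjusted over the list alone, median 0.38, adjusted p = 0.00202, and adjusted p = 0.292 with an estimated correlation). Nupr1 (2.30) and Chac1 (1.18) were higher, and Sesn2 (-0.41) and Ddit4 (-1.33) were lower. Of 7 mitochondrially encoded genes 0 were called over all genes and 5 were higher adjusted over the list alone (median 0.72; adjusted p = 0.0151, and adjusted p = 0.585 with an estimated correlation).

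Retinoic acid response genes were lower in KO in 14 of 25 cases and higher in 2 (15 and 2 adjusted over the list alone, median -0.80, adjusted p = 0.000125, and adjusted p = 0.435 with an estimated correlation). The nuclear receptor gene Nr2f1 (-2.24, SE 0.591, FDR 0.0273) was lower, while Cyp26a1, an enzyme that clears retinoic acid (1.04, SE 0.230, FDR 0.0135; 1.32 in clone 2 and 0.30 in clone 4), and Gbx2 (0.58) were higher. Hox genes, which pattern the body axis and respond to retinoic acid, were lower in 13 of 25 cases and higher in 0 (16 and 0 adjusted over the list alone, median -0.97, adjusted p = 1.13e-07, and adjusted p = 0.490 with an estimated correlation). Examples were Hoxd1 (-1.89), Hoxc5 (-1.84), Hoxb2 (-0.80) and Hoxb4 (-0.53). The neuroectoderm list was lower by its test (4 lower and 2 higher of 26; 5 and 2 adjusted over the list alone, median -1.0, adjusted p = 0.00130, and adjusted p = 0.585 with an estimated correlation). Sox11 (-1.55) and Isl1 (-1.68) were lower, Dll1 (1.55; 1.95 in clone 2 and 0.35 in clone 4) and Sox1 (0.87) were higher, and Pax6 was not called (-0.87, FDR 0.0508).

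Trophoblast genes were lower in 8 of 13 cases and higher in 1 (9 and 1 adjusted over the list alone, median -1.30, adjusted p = 1.63e-05, and adjusted p = 0.114 with an estimated correlation). Tfap2c (-2.26, SE 0.220, FDR 0.00135) and Cdx2 (-0.88) were lower and Tead4 was higher (1.30). Imprinted genes, expressed from 1 parental copy, were lower in 18 of 29 cases and higher in 0 (22 lower and 1 higher adjusted over the list alone, median -1.17, adjusted p = 5.42e-10, and adjusted p = 0.292 with an estimated correlation). Besides Nnat, Dlk1 stood at 81.1 ± 47.4 CPM in KO against 354 ± 90.1 CPM in WT (log2 -2.12), and Gnas (-0.90) and Sgce (-0.69) were lower. Targets of p53 were lower in 8 of 25 cases and higher in 2 (11 and 2 adjusted over the list alone, median -0.44, adjusted p = 0.00256, and adjusted p = 0.585 with an estimated correlation). Bbc3 (-1.66) and Perp (-1.49), which act in apoptosis, were lower, and Plk3 (0.68) and Pmaip1 (0.62) were higher.

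The other 8 lists were not called at 0 h. Fibroblast feeder markers, which would show feeder cells, were higher in 7 of 18 cases and lower in 0 (9 and 1 adjusted over the list alone, median 0.74, adjusted p = 0.186), and in the clones alone 14 of 19 were higher and 0 lower in clone 4 (median 1.85), against 9 higher and 9 lower in clone 2 (median 0.43, mean -0.05). Fbln2 (2.39), S100a4 (2.37), Prrx1 (1.86) and Dcn (1.75) were among those higher. Primitive streak and mesoderm genes were mixed (4 higher and 6 lower of 19; 4 and 7 adjusted over the list alone, median -0.61, adjusted p = 0.378), with Snai1 (1.36) and Meox1 (1.15) higher and Gata5 lower (-2.12). Immediate early genes were also mixed (7 higher and 7 lower of 32; 7 and 11 adjusted over the list alone, median -0.17, adjusted p = 0.345), with Spry2 (1.63) and Ier3 (1.06) higher and Jun (-0.97) and Id3 (-1.55) lower.

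CAPRIN1 partners and stress granule genes were higher in 2 of 32 cases, Larp4b (0.43) and Pabpc4 (0.40), and lower in 0 (0 and 0 adjusted over the list alone, median 0.13, adjusted p = 0.326). G3bp1 (0.06, FDR 0.747), G3bp2 (0.18, FDR 0.389) and Caprin2 (0.27, FDR 0.227) were not called. RNA decay factors were higher in 7 and lower in 4 of 64 cases (4 and 3 adjusted over the list alone, median 0.07, adjusted p = 0.439). Dis3, an exosome nuclease (1.51), and Zfp36l2 (1.07) were higher, although Dis3 was at 0.01 in clone 4, and Zfp36l1 (-0.58) and Dcp1b (-0.73) were lower. The nucleases Xrn2 (0.28, FDR 0.102) and Xrn1 (-0.12, FDR 0.520) were not called. Ribosomal protein genes were higher in 6 and lower in 0 of 83 cases (2 and 0 adjusted over the list alone, median 0.08, adjusted p = 0.0705), among them Rpl39l (2.14), Rpl10l (0.73), Rpl35 (0.40) and Rpl23 (0.37). Cell cycle genes were higher in 2 and lower in 2 of 33 cases (2 and 1 adjusted over the list alone, median -0.12, adjusted p = 0.316), with Cdk2 (0.56) and Ccna2 (0.44) higher and the inhibitors Cdkn1a (-0.67) and Cdkn1c (-1.13) lower. Ccnd2 was not called with the clones pooled (-0.15, FDR 0.739): it was -0.70 in clone 2 (FDR 0.000132) and 0.57 in clone 4 (FDR 0.00773). Myc was at -1.58 (FDR 0.0826), with -2.84 in clone 2 and -0.43 in clone 4. The 3 measured Y-linked genes were not called (0 and 0 adjusted over the list alone, median -1.08, adjusted p = 0.439).

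**Figure D2:**
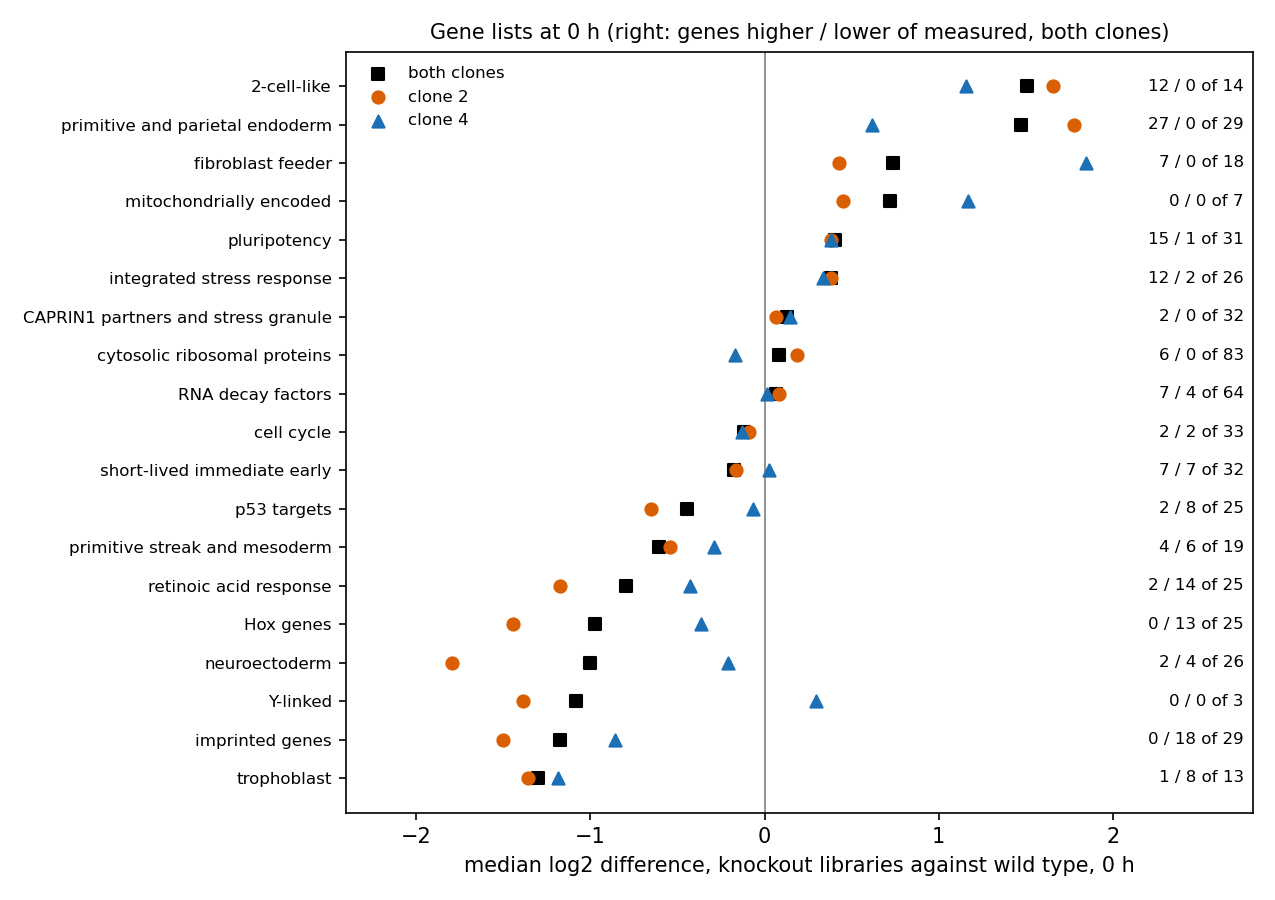
Median log2 difference from WT at 0 h (x axis) of the measured genes of each of the 19 fixed lists (y axis), for both clones together (squares), clone 2 (circles) and clone 4 (triangles); text at the right gives members higher and lower of those measured. Endoderm and 2-cell-like genes lie near 1.5, while imprinted and trophoblast genes lie below -1.

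The count at 0 h rested on few libraries: without clone 4 replicate 2 it was 7582, and it was 1734 without clone 2 replicate 2, 1809 without clone 2 replicate 1, 2209 without WT replicate 2, 2384 without WT replicate 1 and 2642 without WT replicate 3. With the replicate number as a block it was 0 (4609 genes at unadjusted p under 0.05), while DESeq2 kept each of the 79 named genes it could test.

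Of the 81 named genes called at 0 h with the clones pooled, 28 were called in clone 2 and not in clone 4, whose 1 library gives less power, and 28 of these had the same sign in both. They were Pou5f1, Nodal, P4ha2, Plat, Zfp352, Cyp26a1, Gbx2, Hoxb2, Dll1, Sox1, Isl1, Cdx2, Snai1, Meox1, Gata5, Jun, Larp4b, Pabpc4, Dis3, Zfp36l1, Dcp1b, Rpl10l, Rpl23, Sesn2, Cdk2, Ccna2, Cdkn1a and Gnas.

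Each clone also differed from WT when compared alone. In clone 2, 3926 genes were higher and 3814 lower than in WT at 0 h, of 17130 tested, and in clone 4, 1589 were higher and 1130 lower. The clones differed from each other in 4093 genes at 0 h (2293 higher and 1800 lower in clone 4, with 1 library), and with 2 libraries each in 6762, 6688 and 8409 genes at 2, 4 and 8 h. Genes higher in both clones numbered 1027, where independent calls would give 364, and genes lower in both 841 (252), while 161 went opposite ways. Log2 differences of the clones correlated across genes with r = 0.531, and genes are not independent replicates. Since both clones were set against the same WT libraries, part of this is built in: simulated data without a clone effect gave r = 0.276 and a covariance of 0.0370, against 0.456 observed, a difference of 0.419. With a separate pair of WT libraries for each clone, r was 0.426 to 0.504 and the covariance 0.419 to 0.452. The counts of genes called in both clones, the same way or opposite ways, moved widely with the choice of pairs. The clone 4 count at 0 h has 1 library and assumes that it varies like the other groups. That count was 1720 without clone 2 replicate 1 and 1770 without clone 2 replicate 2, and the clone 2 count was 4869 without clone 2 replicate 1.

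Genotype differences were also tested under α-amanitin, and endoderm and imprinted genes again differed. Endoderm genes were higher in KO in 27 of 28 cases at 2 h (median 1.31, adjusted p = 8.63e-10), 27 of 29 at 4 h (1.44, 2.55e-09) and 21 of 29 at 8 h (1.33, 1.69e-08), and lower in 0 at each time. Imprinted genes were lower in 19 of 29, 18 of 28 and 10 of 29 cases (medians -1.23, -1.17 and -0.90). With an estimated correlation, adjusted p was 0.599, 0.459 and 0.748 for endoderm and 0.130, 0.355 and 0.480 for imprinted genes. At 2 h only, calls held with an estimated correlation for pluripotency (adjusted p = 0.0423), trophoblast and 2-cell-like genes (0.0336 each) and the integrated stress response (0.0343); whether the times differ in this was not tested. In all, 2239 genes were higher and 1924 lower in KO at 2 h (of 13195), 2579 and 2257 at 4 h (of 13324) and 1394 and 960 at 8 h (of 13599).

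These totals moved with single libraries. At 2 h the total of 4163 was 2517 without WT replicate 2, 2674 without WT replicate 4 and 2720 without WT replicate 1. At 4 h the total of 4836 was 3069 without WT replicate 3 and 3124 without WT replicate 1. At 8 h the total of 2354 was 619, 673, 652 and 892 without WT replicates 1, 2, 3 and 4, 1376 and 1312 without clone 2 replicates 1 and 2, and 3589 without clone 4 replicate 2. Covariance between the clones exceeded its simulated value by 0.340 at 2 h, 0.384 at 4 h and 0.244 at 8 h.

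The next comparison followed WT cells over 8 h of α-amanitin. Counts give the composition of the RNA and not its amount, so a gene whose RNA was lost as fast as the average shows no change. The largest decreases were in genes induced by retinoic acid. Dhrs3, a retinaldehyde reductase (ENSMUSG00000066026.14; chromosome 4, 144892534 to 144928209), went from 113 ± 9.11 to 3.92 ± 0.286 CPM (SD, n = 4 each; log2 -4.84, SE 0.244, FDR 1.18e-13). Cyp26b1, which clears retinoic acid (ENSMUSG00000063415.12; chromosome 6, 84571414 to 84593908), went from 361 ± 21.4 to 15.7 ± 0.689 CPM (log2 -4.53, SE 0.436, FDR 6.30e-08). Hoxb1, a hindbrain patterning gene (ENSMUSG00000018973.2; chromosome 11, 96365746 to 96368254), went from 28.2 ± 3.70 to 1.64 ± 0.300 CPM (log2 -4.10, SE 0.193, FDR 5.66e-14).

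Further decreases were in the retinoic acid receptor Rarb (-3.17, SE 0.317, FDR 6.88e-08), Rec8 (-2.92), Cdx1 (-2.71), Hoxa4 (-2.62) and Hoxa5 (-2.57). The share of Plaur, the urokinase receptor (ENSMUSG00000046223.10), rose from 20.5 ± 2.78 to 69.3 ± 7.72 CPM (log2 1.77, SE 0.112, FDR 1.76e-11). Plxna4 (2.27, SE 0.541, FDR 0.00249), Irs4 (2.18), Ptgs2 (2.17, FDR 0.0421), Megf10 (1.95), Id4 (1.86), Ttn (1.75) and Il6ra (1.70) also rose. At 8 h, 2210 genes rose and 2232 fell of 14944 tested (935 and 787 at 2 h, 2363 and 2699 at 4 h). Each time has its own count table, so hours and table cannot be told apart. The error of this fit holds the unlike KO clones. The 4 h table stood apart in ribosomal protein genes, of which 68 of 82 fell and 2 rose in WT at 4 h: they took 1.04 ± 0.0761% of counts there (SD, n = 8), against 2.66 ± 0.0335% at 2 h and 2.39 ± 0.116% at 8 h. The 8 h total of 4442 was 2396 without WT replicate 2 and 2589 without WT replicate 1, and the 2 h total of 1722 was 881, 925 and 1015 without WT replicates 2, 1 and 3.

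**Figure D3:**
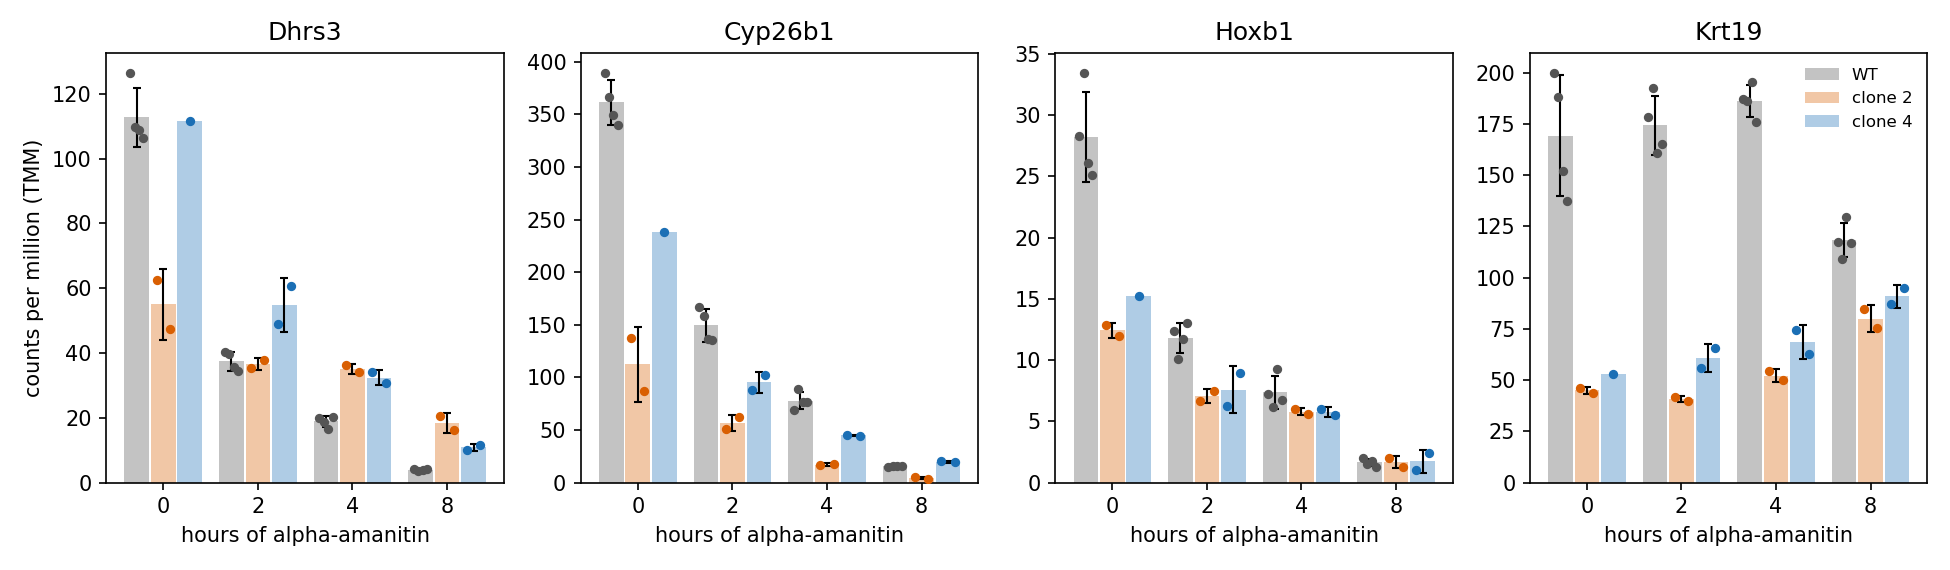
TMM-scaled counts-per-million (y axis) of Dhrs3, Cyp26b1, Hoxb1 and Krt19 in each library by hours of α-amanitin (x axis) for WT, clone 2 and clone 4; bars are means, points are libraries and error bars are SD. In WT, Dhrs3 goes from 113 CPM at 0 h to 3.92 CPM at 8 h.

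Scaling to mitochondrially encoded genes, whose transcription α-amanitin does not block, shifted the median of all genes in WT by -0.77 at 2 h, -1.17 at 4 h and -0.36 at 8 h. With that scaling 72 genes were higher and 9265 lower at 2 h, 108 and 12297 at 4 h, and 80 and 1997 at 8 h, so that higher genes were 0.771%, 0.871% and 3.85% of those called. The share of counts in mitochondrially encoded genes in WT was 0.568 ± 0.180% at 0 h, 0.830% at 2 h, 1.08% at 4 h and 0.657% at 8 h. Directions over time are therefore given relative to the median gene. Of named genes called at 8 h under TMM, Zfp42, Rpl15 and G3bp2 had a log2 change below 0 with mitochondrial scaling (-0.02, -0.09 and -0.02).

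Retinoic acid response genes fell in 14 of 25 cases by 8 h and rose in 2 (14 and 2 adjusted over the list alone, median -0.96, adjusted p = 1.07e-08, and adjusted p = 0.184 with an estimated correlation). Aldh1a2, which makes retinoic acid (1.38), and Rdh10 (0.68) rose. Hox genes fell in 16 of 25 cases and rose in 0 (21 and 0 adjusted over the list alone, median -1.37, adjusted p = 1.19e-12, and adjusted p = 0.275 with an estimated correlation); the smallest called decreases were in Hoxb8 (-0.98) and Hoxa7 (-1.05). Cell cycle genes fell in 13 of 33 cases and rose in 0 (14 and 0 adjusted over the list alone, median -0.28, adjusted p = 0.000514, and adjusted p = 0.428 with an estimated correlation), among them the licensing factor Cdt1 (-1.07), E2f1 (-0.80) and Mcm6 (-0.28). Ribosomal protein genes fell in 11 and rose in 2 of 82 cases (9 and 1 adjusted over the list alone, median -0.16, adjusted p = 0.00139, and adjusted p = 0.790 with an estimated correlation). Rpl27a (-0.56) and Rpl41 (-0.53) fell and Rpl30 (0.35) and Rpl15 (0.22) rose. Genes of the 2-cell-like state rose in 7 of 14 cases and fell in 0 (7 and 0 adjusted over the list alone, median 0.60, adjusted p = 0.00139, and adjusted p = 0.184 with an estimated correlation), among them Zscan4c (1.13) and Usp17la (1.07). All 5 calls held with mitochondrial scaling, where the medians relative to all genes were -0.95, -1.32, -0.27, -0.18 and 0.65, and with culture as a block.

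Short-lived immediate early genes moved early. At 2 h, 16 of 33 had risen and 2 had fallen (median 1.01), at 4 h 19 and 2 (median 0.59), and by 8 h 1 had risen and 7 had fallen (1 and 7 adjusted over the list alone, median -0.16, adjusted p = 0.0684); the list test was made at 8 h. With mitochondrial scaling, 9 were higher and 7 lower at 2 h, and their median relative to all genes was 1.02. At 8 h Klf6 was higher (0.58) and Socs3 (-0.91) and Jund (-0.86) were lower. In KO cells, 16 of 33 had also risen and 1 had fallen at 2 h (median 0.93).

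The other 13 lists were not called by 8 h in WT. CAPRIN1 partners rose in 14 and fell in 2 of 32 cases (14 and 4 adjusted over the list alone, median 0.13, adjusted p = 0.0684), with Fmr1 (0.63), Larp4 (0.61) and G3bp2 (0.27, FDR 0.0154) higher and Ubap2 (-0.33) lower; with mitochondrial scaling their median was -0.21 before, and 0.15 after, the median of all genes was taken off. RNA decay factors rose in 13 and fell in 8 of 64 cases (14 and 8 adjusted over the list alone, median 0.01, adjusted p = 0.650), with Smg1 (0.69) and Exosc1 (0.53) higher and Dis3l2 (-0.58) and Khsrp (-0.54) lower. Xrn2 (0.06, FDR 0.515), Xrn1 (0.17, FDR 0.187), G3bp1 (-0.04, FDR 0.810), Ccnd2 (-0.36, FDR 0.486) and Myc (-0.72, FDR 0.321) were not called in the joint fit. With WT libraries alone Ccnd2 (-0.37, FDR 3.41e-05), Myc (-0.71, FDR 3.75e-06), Gata6 (-0.46, FDR 4.15e-06), Caprin2 (-0.33, FDR 0.00712) and Pou5f1 (-0.28, FDR 0.0342) were called lower. Pluripotency genes rose in 3 and fell in 7 of 31 cases (3 and 7 adjusted over the list alone, median -0.21, adjusted p = 0.0677). Lefty1 (-1.26) and Tdgf1 (-1.16) fell, Zfp42 (0.35) rose, and Pou5f1 (-0.27, FDR 0.145) and Nanog (-0.12, FDR 0.492) were not called. At the preset correlation this list passed the threshold with culture as a block (adjusted p = 0.0295) and with mitochondrial scaling (adjusted p = 0.0263), while in the joint fit an estimated correlation gave adjusted p = 0.715.

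Integrated stress response genes rose in 5 and fell in 6 of 26 cases (6 and 7 adjusted over the list alone, median 0.02, mean -0.11, adjusted p = 0.908), with Nars (0.55) and Psat1 (0.53) higher and Cebpb (-1.09) and Ddit4 (-0.92) lower. Targets of p53 rose in 2 and fell in 2 of 25 cases (2 and 2 adjusted over the list alone, median 0.13, adjusted p = 0.596), with Rrm2b (1.03) and Tigar (0.45) higher and Bbc3 lower (-0.78). Endoderm genes rose in 3 and fell in 1 of 29 cases (3 and 1 adjusted over the list alone, median -0.02, mean 0.06, adjusted p = 0.825), with Afp (1.77), Thbd (0.98) and Lrp2 (0.89) higher and Apoe lower (-0.44). Gata6 was not called in the joint fit (-0.45, FDR 0.189). Mesoderm genes rose in 2 and fell in 4 of 15 cases (2 and 5 adjusted over the list alone, median -0.25, adjusted p = 0.300), with Kdr (1.31) and Tbx20 (0.68) higher and Foxf1 (-1.33) and Lhx1 (-2.24) lower. Trophoblast genes rose in 2 and fell in 3 of 13 cases (2 and 3 adjusted over the list alone, median -0.22, adjusted p = 0.602), with Tead4 higher (0.55) and Tfap2c (-1.0) and Gcm1 (-1.07) lower. Neuroectoderm genes rose in 2 and fell in 3 of 25 cases (2 and 2 adjusted over the list alone, median -0.15, adjusted p = 0.650), with Elavl4 (1.07) and Ncam1 (0.56) higher and Sox3 (-0.92) and Pax6 (-0.84, FDR 0.00993) lower. Imprinted genes rose in 3 and fell in 7 of 29 cases (5 and 7 adjusted over the list alone, adjusted p = 0.650), with a median of 0.01 while the test leaned down; Zdbf2 (1.18) and Kcnq1ot1 (0.90) rose and Meg3 (-0.84) and Rtl1 (-1.0) fell. Of the fibroblast (19 measured, median 0.17, adjusted p = 0.775), mitochondrially encoded (7, 0.25, 0.311) and Y-linked genes (4, 0.18, 0.650), 0 were called, over all genes or adjusted over the list alone.

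In KO cells 428 genes rose and 354 fell at 2 h, 2266 and 2434 at 4 h, and 1037 and 1285 at 8 h. Retinoic acid response genes fell in 10 and rose in 1 of 25 cases by 8 h (median -0.61), and Hox genes fell in 11 and rose in 0 of 25 (median -0.89). With the KO culture as a block, which removes the difference between the clones, 2274, 7223 and 5364 genes were called. The 2 h total of 782 was 336 and 352 without clone 2 replicates 1 and 2, the 4 h total of 4700 was 3114 without clone 2 replicate 2, and the 8 h total of 2322 was 1224 and 1163 without clone 2 replicates 1 and 2. With mitochondrial scaling the median gene moved by -0.20, -0.66 and 0.01, and 17 genes were higher and 20 lower at 2 h, 157 and 6448 at 4 h, and 41 and 75 at 8 h.

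A further comparison asked whether RNA changed differently over α-amanitin in KO and WT, as altered RNA stability or transcription could give. Below, relatively higher or lower refers to the change and not to the level. By 8 h, 2 genes differed, both relatively higher in KO. Dhrs3 fell less in KO, from 73.9 ± 33.6 CPM (SD, n = 3) to 14.7 ± 4.71 CPM (n = 4), than in WT, a log2 difference of the changes of 2.51 (SE 0.320, FDR 0.000361; 3.23 in clone 2 and 1.47 in clone 4). Krt19, an epithelial keratin (ENSMUSG00000020911.14; chromosome 11, 100140810 to 100145926), went from 47.6 ± 4.56 to 85.4 ± 8.00 CPM in KO and from 169 ± 29.4 to 118 ± 8.42 CPM in WT, a difference of 1.36 (SE 0.200, FDR 0.00238; 1.33 and 1.28). At 2 h the 5 genes called, chosen after their values were seen, were relatively lower in KO. They were Arid5b (-0.58), Dusp10 (-1.0), Plaur (-0.89), Socs3 (-0.86) and Timp3 (-1.01). In KO at 0 h Krt19 was lower and Plaur higher (56.7 against 20.5 CPM), and their calls cannot be told apart from this. At 4 h 3 genes were relatively higher and 12 relatively lower in KO, and the joint F test over the 3 times called 53. Both sets include ribosomal protein genes (Rps7, Rpl35, Rpl7a and Rps3a1, chosen after their values were seen). The share of such genes fell in the whole 4 h table, so part of these calls may reflect that table.

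With the clones pooled, none of the genes named whatever their values differed in change over 8 h, including Xrn2 (-0.22, FDR 0.419), Nanog (-0.56, FDR 0.254) and Myc (0.89, FDR 0.753). With each clone as its own group Nanog was relatively lower in KO (-0.54, FDR 0.0181) and Myc relatively higher (0.54, FDR 0.0202); with culture as a block Nanog (FDR 0.0321) and G3bp2 (-0.33, FDR 0.0397) were called relatively lower and Myc was not called (FDR 0.0563). Unadjusted p-values were under 0.05 for 401, 814 and 1587 genes at 2, 4 and 8 h and for 1548 in the F test. The error in these fits holds the difference between the clones. With each clone as its own group, 154, 435 and 1269 genes differed in the mean of the clones (465 relatively higher and 804 lower at 8 h), although 9.74% of calls in a simulation of that fit fell on unchanged genes, and with culture as a block 68, 334 and 996. Mitochondrial scaling left 0, 0 and 1 (1029, 1138 and 695 genes at unadjusted p under 0.05) and shifted the median gene by 0.55, 0.50 and 0.37; Krt19 was no longer called under it, nor without WT replicate 1 or WT replicate 2. DESeq2 with its own size factors called 14, 31 and 49. The 8 h count was 33 without clone 4 replicate 2, 5 without clone 4 replicate 1 and 1 without WT replicate 1 or WT replicate 2.

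Of the 19 lists, 4 differed in their change over 8 h. Retinoic acid response genes (1 higher, 0 lower of 25; 1 and 1 adjusted over the list alone, median 0.39, adjusted p = 0.000590, and adjusted p = 0.763 with an estimated correlation) and Hox genes (0 and 0 of 25; 1 and 0 adjusted over the list alone, median 0.51, adjusted p = 0.000283, and adjusted p = 0.781 with an estimated correlation) were relatively higher in KO. Genes of the 2-cell-like state were relatively lower (0 and 0 of 14; 0 and 2 adjusted over the list alone, median -0.63, adjusted p = 3.86e-05), and this held with an estimated correlation (adjusted p = 0.0337), though not with each clone as its own group (adjusted p = 0.222 with an estimated correlation). CAPRIN1 partners were relatively lower by a small amount (0 and 0 of 32; 0 and 0 adjusted over the list alone, median -0.10, adjusted p = 0.0166, and adjusted p = 0.763 with an estimated correlation), a call that mitochondrial scaling ended (adjusted p = 0.638). With culture as a block the same 4 lists were called (adjusted p = 0.000297, 0.000551, 0.000297 and 0.0199), and fibroblast markers as well (adjusted p = 0.00935). The 0 h libraries enter each difference of the changes with the opposite sign. Retinoic acid response and Hox genes were lower and 2-cell-like genes higher in KO at 0 h, each opposite to its difference in change. The calls of these lists can thus not be told apart from the difference at 0 h.

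The other 15 lists were not called in the difference of the changes over 8 h, and 0 of their members differed over all genes tested. Pluripotency genes had a median of -0.21 (0 higher and 4 lower of 31 adjusted over the list alone, adjusted p = 0.0571). Mesoderm genes had a median of 0.30 (1 higher and 0 lower of 15 adjusted over the list alone, adjusted p = 0.121). In the remaining lists 0 members differed adjusted over the list alone. Medians were positive for immediate early genes (0.19, adjusted p = 0.0954), p53 targets (0.15, 0.11), imprinted genes (0.25, 0.11), neuroectoderm (0.25, 0.490), trophoblast (0.39, 0.550), fibroblast markers (0.25, 0.723), cell cycle (0.07, 0.386), ribosomal proteins (0.03, 0.386) and the integrated stress response (0.01, 0.550). They were negative for mitochondrially encoded genes (-0.35, adjusted p = 0.11), endoderm (-0.09, 0.225), RNA decay factors (-0.04, 0.341) and Y-linked genes (-0.03, 0.645). Mitochondrial scaling called endoderm as relatively lower in KO at the preset correlation (adjusted p = 0.00967), the only correlation used with that scaling.

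The RIP lists, from CAPRIN1 immunoprecipitates, are named CNT vs RA and 2I vs RA and give neither direction nor values. CNT is assumed here to mean the control, and RA retinoic acid. The labels name Caprin1 KO cells as the control and nocodazole, arsenate and ESC medium as further RIP conditions, and do not say which of these 2I stands for. The CNT list held 2170 symbols and the 2I list 2502, with 1342 in both (61.8% of the CNT list and 53.6% of the 2I list). Cytosolic ribosomal protein genes set them apart: 3 of 86 were in the CNT list (Rpl15, Rpl3 and Rpl6) and 45 in the 2I list. Pluripotency genes numbered 4 of 32 in the CNT list (Dnmt3l, Klf4, Sall4 and Tbx3) and 15 in the 2I list, Nanog, Esrrb and Klf5 among them. CAPRIN1 partners numbered 15 and 13 of 32, RNA decay factors 20 and 20 of 65, endoderm genes 12 and 12 of 30 and retinoic acid response genes 5 and 5 of 25. None of the Hox, 2-cell-like or mitochondrially encoded genes was in either list. Caprin1 and Xrn1 were in both lists, Xrn2, Ccnd2 and G3bp2 in the CNT list alone, and G3bp1 and Nanog in the 2I list alone. Myc, Caprin2, Pou5f1, Gata6 and Pax6 were in neither. The lists state no background, and enrichment was not tested.

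Genes of the CNT list were slightly higher in KO than in WT at 0 h. Of 2109 measured, 535 were higher and 214 lower (588 and 250 adjusted over the list alone), with a median log2 difference of 0.12 (camera p = 0.00233, adjusted p = 0.00466; adjusted p = 0.0473 with an estimated correlation), and the call was lost without clone 4 replicate 2, the only clone 4 library at 0 h (adjusted p = 0.0550). The medians were 0.11 in clone 2 (p = 0.0306, adjusted p = 0.0612) and 0.14 in clone 4 (p = 0.000286, and adjusted p = 0.0810 with an estimated correlation). Genes of the 2I list were mixed, with 496 higher and 310 lower of 2413 (533 and 347 adjusted over the list alone, median 0.03, adjusted p = 0.278). Camera gave p = 0.145 at 2 h, p = 0.00406 at 4 h (p = 0.163 with an estimated correlation) and p = 0.0498 at 8 h (adjusted p = 0.0996) for the CNT list in KO against WT.

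Over 8 h in WT, CNT genes rose in 512 and fell in 204 of 2105 cases relative to the median gene (526 and 213 adjusted over the list alone, median 0.11, p = 0.000496, and adjusted p = 0.0711 with an estimated correlation). For the 2I list 405 rose and 412 fell of 2399 (416 and 429 adjusted over the list alone, adjusted p = 0.976), with a median of 0.01 and a mean of -0.04. In the difference of the changes, CNT genes were relatively lower in KO by a median of -0.05 (1 higher and 0 lower; 1 and 2 adjusted over the list alone; p = 0.0197, adjusted p = 0.0394), which was lost with an estimated correlation (p = 0.149, adjusted p = 0.297). The 2I list showed no difference past the threshold (0 and 0; 2 and 4 adjusted over the list alone, adjusted p = 0.623), and its median of -0.0004 and mean of 0.02 differed in sign. Against 10000 random lists matched on expression and gene length, which take no account of correlation between genes, the 2I median lay above 0% in WT at 8 h (random mean 0.06) and above 100% in the difference of the changes (random mean -0.03), and the CNT median above 100% and 0.1% (0.07 and -0.04). The CNT list was higher in KO at 0 h, and the 0 h libraries enter the difference of the changes with the opposite sign.

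**Figure D4:**
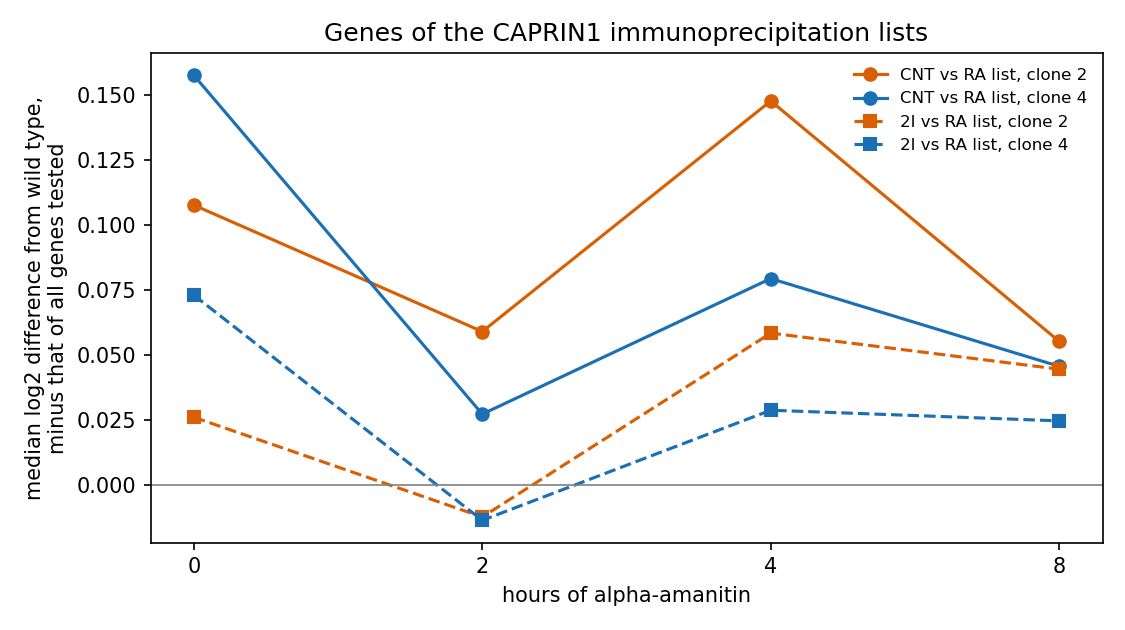
Median log2 difference from WT of genes in each RIP list minus the median of all genes (y axis) by hours of α-amanitin (x axis), for clone 2 and clone 4; the CNT list is solid and the 2I list dashed. At 0 h the medians of the CNT list, before the median of all genes was taken off, were 0.11 in clone 2 and 0.14 in clone 4.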

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

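The regroupings of libraries, the limit for single libraries and the tests of a difference between groups reported here were chosen before the data were examined, and the fits of each clone alone, of WT or KO libraries alone, and the genotype term kept when cultures were regrouped, were chosen after results were seen.

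Among 28 groups of library measures tested for a library far from the others, 2 passed the limit, where chance gives about 1 in 20. The share of counts in ribosomal protein genes was 3.03% in WT replicate 2 at 0 h and 2.66 to 2.70% in the other WT libraries of that time. The share in mitochondrially encoded genes was 0.493% in WT replicate 3 at 8 h and 0.695 to 0.730% in the others. For the named genes, 39 of 1113 groups (3.5%) had such a library, and the library found most often, WT replicate 1 at 0 h, stood apart in 4.

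Effects differed between groups by a test of the difference in the following results. The change under α-amanitin differed between KO and WT in 5 genes at 2 h, 15 at 4 h and 2 at 8 h, and in 53 by the joint F test. Over 8 h Dhrs3 (log2 2.51) and Krt19 (1.36, lower at 0 h) were relatively higher in KO. Between clone 4 and clone 2, 6762, 6688 and 8409 genes differed at 2, 4 and 8 h, with 2 libraries each. The 4093 genes at 0 h rest on 1 library of clone 4, taken to vary like the other groups. Of the changed genes at 4 h outside the rule for named genes, chosen after their values were seen, Tuba1b (-0.96), Rps7 (-1.04), Rpl35 (-1.04) and Kdr (-1.35) were relatively lower in KO and Rps3a1 was relatively higher (1.60). The counts at 4 h and in the F test include ribosomal protein genes whose counts fell in the whole 4 h table. With the real genotype kept in the fit, so that its difference in level stays out of the error, the 8 cultures were regrouped 4 against 4 in 35 ways. The real grouping alone gave counts as large at 2, 4 and 8 h and in the F test (1 of 35 each, highest other 0, 0, 0 and 1). This would speak against chance only if replicate numbers marked the same culture over time. In WT 3 of 24 such pairs passed 0.1, and in KO the same number was the best match in 11 of 21. The regrouping can therefore not exclude chance for these totals. The totals rest on single libraries: leaving out each in turn gave 0 to 11 genes at 2 h, 4 to 57 at 4 h, 1 to 33 at 8 h and 5 to 79 in the F test, the highest each time without clone 4 replicate 2 and the lowest without WT replicate 1 at 2, 4 and 8 h, there with ties, and without clone 2 replicate 2 in the F test. With clone 2 alone 184, 1035 and 1176 genes differed at the 3 times and with clone 4 alone 82, 98 and 649.

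For KO against WT at each time, 1 of 35 splits of the libraries, the real one, gave as many genes. The counts were 4092, 4163, 4836 and 2354 at 0, 2, 4 and 8 h, and the highest other was 0 each. The splits treat libraries as exchangeable, while the KO libraries pair by cell line. A split that mixes WT with the clones also puts their differences into its error. This test can therefore not exclude chance differences between cell lines. In fits of only the WT libraries of the 2 times compared, the real split was also the only one with as many genes. For 2, 4 and 8 h against 0 h this was 1 of 35 each (2465, 6092 and 6243 genes, highest other 0, 0 and 5). In fits of only the KO libraries of the 2 times compared, 2 of 35 splits gave as many genes as the real one at each time (85, 2434 and 171 genes), and the highest other, at 6505, 4312 and 5928 genes, was the split by clone. That split points to a structure of the samples, since the clones are separate cell lines; with culture as a replicate block the real counts were 2274, 7223 and 5364.

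Chance could not be excluded for the number of fixed lists called. At 0 h, 8 of 35 splits of the KO and WT libraries gave as many lists as the real 11 (highest other 11). For WT 8 h against 0 h in the WT libraries of these times, 14 of 35 gave as many as the real 6 (highest other 9), and for the difference in change over 8 h, 22 of 35 gave as many as the real 4 (highest other 12). For the RIP lists, 4 of 35 splits gave a p for the CNT list at 0 h as small as the real 0.00233 (smallest other 0.000385) and 11 for the 2I list (0.278; smallest other 0.0190). In the difference of the changes it was 11 for the CNT list (0.0197; smallest other 0.000248) and 26 for the 2I list (0.623; smallest other 0.00359).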

How the results depend on the processing

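The fits without the 4 h libraries, with WT libraries alone, with clone 2 or clone 4 alone and the list tests with each clone as its own group were chosen after the data were seen; the other alternatives were chosen before. DESeq2 and RLE size factors kept the counts for KO against WT at each time, for each clone against WT and for WT and KO over time within 1.5 times those of edgeR. Of 81 named genes called at 0 h, RLE size factors lost Gbx2, the joint fit 4, the limit of 1.5-fold 11 and no filter 19, and DESeq2 lost 0 of the 79 it could test; without single libraries 0 to 39 were lost, and 0 of the called genes reversed. Of 77 called in WT at 8 h, DESeq2 lost 3, no filter 18, mitochondrial scaling 32 and culture as a block 0, and 0 to 30 were lost without single libraries. Simulated 2-fold changes between KO and WT were recovered in 56.1 to 63.6% of cases at the depth of the 2 to 8 h tables. The simulated spread was estimated with the unlike clones in 1 group. The alternatives that use the RIP lists' own p-values, direction or fold change, and another pseudocount, were not run, because the lists hold symbols alone and the tables hold counts. Causes of the differences that follow were not tested, except that settings which take the clone difference out of the error have less error by construction.

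With the replicate number as a block, KO against WT gave 0, 2, 0 and 0 genes by edgeR at 0, 2, 4 and 8 h (4609, 3148, 3618 and 1708 at unadjusted p under 0.05; DESeq2 without a block 4616, 4488, 5139 and 3323). The numbers do not pair these libraries. The mean of the clones in a 3-group fit gave 6540, 8025, 8588 and 8087 genes. A limit of 1.5-fold left 2216, 2620 and 1209 at 2, 4 and 8 h, and the joint fit gave 3560 at 8 h. With culture as a replicate block, 3977, 7707 and 7623 genes changed in WT at 2, 4 and 8 h, 2274, 7223 and 5364 in KO, and 68, 334 and 996 differed in change, with 1503 in the F test. With each clone its own group these were 4396, 8275 and 8097 in WT, 2482, 7355 and 5667 in KO, 154, 435 and 1269 in the difference, and 2076 in the F test. Clone 2 alone gave 184, 1035 and 1176 and clone 4 alone 82, 98 and 649 for the difference. WT libraries alone gave 3656 genes at 2 h and 7096 at 8 h. Without the 4 h libraries, 1 gene differed in change at 2 h.

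Mitochondrial scaling gave 9337, 12405 and 2077 genes in WT at 2, 4 and 8 h, and 37 and 116 in KO at 2 and 8 h. For the difference in change it gave 0, 0 and 1 (1029, 1138 and 695 at unadjusted p under 0.05), with 1 in the F test, where DESeq2 with its own size factors gave 14, 31 and 49 and 183. Without a filter on low counts there were 1095 genes in WT at 2 h, 440 and 1522 in KO at 2 and 8 h, 2 for the difference at 2 h and 23 in the F test.

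Without single libraries, KO against WT at 0 h ranged from 1734 genes (without clone 2 replicate 2) to 7582 (without clone 4 replicate 2), with 1809 without clone 2 replicate 1 and 2209, 2384 and 2642 without WT replicates 2, 1 and 3. At 2 h the range was 2517 (without WT replicate 2) to 4792, with 2674 and 2720 without WT replicates 4 and 1. At 4 h it was 3069 (without WT replicate 3) to 5506, with 3124 without WT replicate 1. At 8 h it was 619 (without WT replicate 1) to 3589 (without clone 4 replicate 2), with 673, 652 and 892 without WT replicates 2, 3 and 4 and 1376 and 1312 without clone 2 replicates 1 and 2. Clone 2 against WT ranged from 4869 (without clone 2 replicate 1) to 7864, and clone 4 against WT from 1720 (without clone 2 replicate 1) to 3258, with 1770 without clone 2 replicate 2. WT at 2 h ranged from 881 (without WT replicate 2) to 2034, with 925 and 1015 without WT replicates 1 and 3, and WT at 8 h from 2396 (without WT replicate 2) to 5033, with 2589 without WT replicate 1. KO at 2 h ranged from 336 (without clone 2 replicate 1) to 833, with 352 without clone 2 replicate 2, KO at 4 h from 3114 (without clone 2 replicate 2) to 5045, and KO at 8 h from 1163 (without clone 2 replicate 2) to 2242, with 1224 without clone 2 replicate 1.

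The difference in change at 2 h ranged from 0 to 11 genes (without clone 4 replicate 2). It was 0 without clone 2 replicate 1 or 2 and without WT replicate 1, 2 or 4 (355, 378, 281, 282 and 513 genes at unadjusted p under 0.05), 1 without WT replicate 3 and 3 without clone 4 replicate 1. At 4 h it ranged from 4 (without WT replicate 1 or 3) to 57 (without clone 4 replicate 2), with 6 without clone 2 replicate 1 or WT replicate 2 or 4 and 9 without clone 2 replicate 2. At 8 h it ranged from 1 (without WT replicate 1 or 2) to 33 (without clone 4 replicate 2), with 5 without clone 4 replicate 1. The F test ranged from 5 (without clone 2 replicate 2) to 79 (without clone 4 replicate 2), with 7, 8, 10 and 24 without WT replicates 1, 2, 3 and 4 and 10 without clone 2 replicate 1.

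With an estimated correlation, camera called 0 lists at 0 h, 0 in WT at 8 h and 1 in the difference in change; by the preset correlation these were 11, 5 and 4. Fry answers another question, whether the genes of a list move one way on balance, and found such a shift in 9, 6 and 1 lists. At 0 h it found one for cell cycle (adjusted p = 0.00876) and none for neuroectoderm (0.0744), p53 targets (0.0973) and mitochondrially encoded genes (0.126). In WT at 8 h it found one for pluripotency (adjusted p = 0.0152) and CAPRIN1 partners (0.00433) and none for ribosomal proteins (0.0937). For the CNT list in the difference in change, p was 0.149 with an estimated correlation, 0.0499 without genes above the 95th percentile of expression, 0.0405 with culture as a replicate block and 0.0325 with RLE size factors, and adjusted over both lists it passed in none of these. It ranged from 0.00483 (without clone 2 replicate 2) to 0.185 (without clone 4 replicate 2), and adjusted over both lists it was also lost without clone 2 replicate 1 (0.0271), WT replicate 3 (0.0294), clone 4 replicate 1 (0.0399), WT replicate 1 (0.0404), WT replicate 4 (0.0432) and WT replicate 2 (0.106). At 0 h its p ranged from 0.000526 (without clone 2 replicate 2) to 0.0275 (without clone 4 replicate 2), where the call was lost after adjustment. By fry, which sets a list against no change, the 2I list was higher in KO at 0 h (adjusted p = 0.0399), while by camera its difference from other genes did not pass the threshold. In the difference in change the fry p for the CNT list was 0.0252 (adjusted p = 0.0505) and for the 2I list fry gave adjusted p = 0.453, leaning down where camera leaned up.

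Genes that were not called reversed sign as follows. G3bp1 at 0 h was -0.0076 in the 3-group fit and ranged from -0.0006 (without clone 2 replicate 1) to 0.18, and Ccnd2, KO vs WT at 0 h, ranged from -0.71 (without clone 4 replicate 2, where it was called) to 0.081 (without clone 2 replicate 1). In WT at 8 h, mitochondrial scaling gave Xrn2 -0.26 and Xrn1 -0.16, and reversed the called genes Zfp42 (-0.017), Rpl15 (-0.094) and G3bp2 (-0.025); Xrn2 ranged from -0.0040 (without WT replicate 2) to 0.14. In the difference in change, Caprin1 was -0.18 with culture as a replicate block, -0.26 with each clone its own group, -0.10 in clone 2 and -0.41 in clone 4, and ranged from -0.32 (without clone 4 replicate 1) to 1.64 (without clone 4 replicate 2). Ccnd2 was -0.17, -0.16, -0.32 and -0.0069 in the same settings and ranged from -0.12 (without clone 4 replicate 1) to 0.41. Mitochondrial scaling gave Xrn2 0.11, Xrn1 0.30, G3bp1 0.29, G3bp2 0.012 and Pou5f1 0.13, and clone 4 alone gave G3bp1 0.029, Gata6 -0.13 and Pax6 -0.0073. Xrn1 ranged from -0.11 to 0.0625 (without WT replicate 2), and Caprin2 from -0.039 (without clone 4 replicate 2) to 0.11.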

Other observations

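The tests in this part were chosen after the patterns they address were seen; those of expression level and length and of the wild-type pairs for the CNT list were set before their own values were seen, the others after.

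Interferon-stimulated genes, which defend cells against viruses, were higher in both clones at each time. In KO against WT, 34 of 38 were higher and 0 lower at 0 h (36 and 0 adjusted over the list alone, median log2 2.30, adjusted p = 7.77e-22, and adjusted p = 0.0108 with an estimated correlation), 29 of 32 at 2 h (median 2.31), 25 of 28 at 4 h (2.05) and 27 of 30 at 8 h (2.34). In clone 2, 35, 32, 33 and 32 were higher at 0, 2, 4 and 8 h, and in clone 4, 35, 34, 35 and 34. With an estimated correlation the list was called in clone 4 at each time (largest adjusted p = 0.0494) but in clone 2 only at 4 h (adjusted p = 0.00496; 0.122, 0.0664 and 0.117 at 0, 2 and 8 h). Of 13449 genes tested at each time, 646 were higher in both clones at all 4 times and 458 lower; 29 of the 34 interferon genes tested were among the higher. Others at the top of that set, chosen after their values were seen, were the cytokine Il6, the chemokines Ccl2 and Cxcl5, the collagenase Mmp13 and the protease Fap, and at the bottom Nnat, Hapln1, Tfap2b and Sox9.

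Over 8 h of α-amanitin in WT, genes of cholesterol synthesis rose in 15 of 23 cases and fell in 0 (16 and 0 adjusted over the list alone, median 0.64, adjusted p = 1.10e-07, and adjusted p = 0.0254 with an estimated correlation). Hypoxia and glycolysis genes fell in 13 of 21 cases and rose in 0 (13 and 0 adjusted over the list alone, median -0.66, adjusted p = 1.10e-07, and adjusted p = 0.0397 with an estimated correlation), antigen presentation genes fell in 9 of 17 and rose in 0 (9 and 0 adjusted over the list alone, median -0.38, adjusted p = 0.0117 with an estimated correlation), and interferon-stimulated genes fell in 9 of 37 and rose in 1 (8 and 1 adjusted over the list alone, median -0.55, adjusted p = 0.0325 with an estimated correlation). At 0 h in KO against WT, the other added lists were not called: antigen presentation 4 higher and 1 lower of 17 (median 0.07, adjusted p = 0.731), cholesterol synthesis 2 and 1 of 23 (-0.12, 0.859; mean 0.08) and hypoxia and glycolysis 4 and 3 of 22 (0.24, 0.859). Hypoxia and glycolysis genes at 0 h were higher in 10 and lower in 3 of 22 cases in clone 2, where the list was not called (median 0.38, adjusted p = 0.0564), and higher in 1 and lower in 9 in clone 4 (median -0.47, adjusted p = 0.00426, lost with an estimated correlation at adjusted p = 0.475). In clone 2 the list was not called at 2, 4 or 8 h either (adjusted p = 0.0559, 0.202 and 0.0905). In clone 4 it was called lower at 2 and 8 h (adjusted p = 0.00357 and 0.0154; 0.182 and 0.465 with an estimated correlation) and not at 4 h (0.223). The difference between the clones in this list was not tested. At 8 h antigen presentation was called higher in KO (5 higher and 0 lower of 15, median 0.22, adjusted p = 0.00680, and adjusted p = 0.0408 with an estimated correlation). There 10 were higher and 0 lower of 16 in clone 4 (adjusted p = 0.000905) and 5 and 2 of 16 in clone 2 (adjusted p = 0.183), and with an estimated correlation it was called in neither alone (adjusted p = 0.162 and 0.596). Cholesterol genes were called higher in KO at 2, 4 and 8 h (adjusted p = 0.0444, 0.0199 and 0.0141), each lost with an estimated correlation (adjusted p = 0.426, 0.513 and 0.149). At 2 h they were higher in clone 4 in 17 of 23 cases and lower in 0 (median 0.68, adjusted p = 0.00817 with an estimated correlation), against 6 higher and 7 lower in clone 2. In clone 4 this held at 4 h (17 and 0 of 23, adjusted p = 0.0286 with an estimated correlation), and at 8 h (13 and 0 of 23) it was lost with an estimated correlation (adjusted p = 0.309). In the difference in change over 8 h, interferon (median 0.40, adjusted p = 0.0184), antigen presentation (0.23, 0.0158) and cholesterol genes (0.07, 0.0158) were relatively higher in KO, all lost with an estimated correlation (adjusted p = 0.200, 0.0904 and 0.266), and hypoxia genes were not called (0.612).

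In clone 4, where Caprin1 stood at the WT level, the lowest median of the interferon list was 1.93. This argues against a lower transcript as the cause in that clone, though the protein was not measured. It was known when the pattern was chosen, and it leaves the cause in clone 2 open. Mislabelled WT libraries stay open, as 34 or more genes higher in clone 4 at each time are the pattern itself. Feeder fibroblasts may contribute in clone 4, where the fibroblast list was higher with a lowest median of 1.46 at 8 h and Fbln2 and Col5a2 were higher by 3.45 and 3.00, although the abundant Col3a1 was at -0.50 and Mmp2 at 0.04; 18 of the 20 listed genes were measured at 8 h, and WT itself had Fn1 at 1923 CPM. In clone 2 the list was mixed (median 0.43 at 0 h, -0.44 at 8 h) and WT expresses it, so feeders stay open. Culture history of the clones cannot be told apart from the knockout, since each clone is 1 cell line (median 0.11 between WT pairs at 0 h).

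The 4 h table differed from the others in abundant genes. Cytosolic ribosomal proteins took 2.72 ± 0.202% of counts at 0 h (SD, n = 7), 2.66 ± 0.0335% at 2 h, 1.04 ± 0.0761% at 4 h and 2.39 ± 0.116% at 8 h (n = 8 each); Gapdh had 876, 810, 13.3 and 689 CPM, Ppia 579, 623, 53 and 576 CPM, and Actb 2747, 3616, 3644 and 3508 CPM. Of 80 genes that fell by over 2 log2 units in WT from 2 to 4 h, 38 were ribosomal proteins. Loss of RNA is argued against by the return of the 80 genes in KO libraries, with a median change of -3.97 from 2 to 4 h and 3.76 from 4 to 8 h (4.43 with mitochondrial scaling), and depth by the mean total of 7.85 M at 4 h, between those at 2 and 8 h. Reads shared with pseudogenes may account for part of it: 65% of the 80 had a namesake pseudogene in the tables, against 2.78% of 719 genes of similar level, as a different treatment of reads with several positions in that table would give. The pseudogenes themselves were mixed, with 7 higher and 4 lower of 19 tested in WT from 2 to 4 h, and Ppia, which fell as well, has no namesake pseudogene there.

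Genes of the CNT list were higher in KO at 0 h by a median of 0.12. Of 10000 random lists matched on expression and gene length, 100% had a lower median (their mean was 0.04), so these properties do not account for it, although listed genes were long (median 12888 against 7724 bases). The list moved by 0.0399 between the WT pairs, which argues against that difference as the source. A dependence on the Caprin1 transcript level cannot be told apart: the median was higher in clone 4, with Caprin1 at the WT level, than in clone 2 at 0 h (0.14 from 1 library, against 0.11) and lower at 2 h (0.02 against 0.07), 4 h (0.07 against 0.14; difference -0.0732) and 8 h (0.04 against 0.05). Since 4 of 35 splits gave a p as small, chance stays open, and a link between binding, if the list holds bound genes, and level is a hypothesis that these data do not settle; the 2I list lay above 13.2% of its random lists.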
